A study of Mus musculus with 8 samples.

How the data were processed

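Ribosome footprints were sequenced from dorsal root ganglia (DRG), the ganglia beside the spinal cord that hold the cell bodies of sensory neurons, of wild-type mice of a strain labelled SW that had received saline. There were 8 libraries, 4 labelled male and 4 labelled female, each with a replicate number from 1 to 4. Per the labels' protocols, ribosome-bound RNA was collected on size-exclusion columns, ribosomal RNA was depleted, fragments of 28 to 34 nt were selected on a gel, and libraries were made with a small RNA kit. Matched libraries of RNA abundance, which the labels also describe, were not used here, so no translational efficiency was computed. Nothing in the labels says that the libraries came from separate animals. If they did not, the p-values measure only the spread between these samples, which may be technical.

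The authors deposited 1 table per labelled sex, both with the same 48431 gene rows. Per the submitters' processing notes, the tools used were FastQC 0.11.5, TopHat2 2.1.1, Bowtie2 2.2.9 and Cufflinks 2.2.1, with the builds GRCm38.p4 and mm10; the role and order of the tools and the gene annotation are not given in the sources used here. The deposited tables are named as TPM, but their values are CPM (reads per 1000000 assigned reads): each column summed to 1000000, and between 95.7% and 96.4% of the values above 0 in a library were whole multiples of 1 step, within a tolerance of 0.01 of a step, where 2% would be whole by chance, and the step did not depend on the gene. A value here is therefore a share of reads per gene with no correction for gene length, and levels of different genes are shares of reads rather than densities. The tests had been planned for TPM, and the same tests on log2 values were kept. Counts can be recovered by dividing by the step, but no count model was fitted, so differences in depth between libraries were not modelled. The step puts the depth at between 3697686 assigned reads, in the library labelled male 1, and 12714554, in the library labelled male 3. One read is worth 0.270 CPM in the former and 0.0787 CPM in the latter, so the floor of 3 reads lies between 0.236 and 0.811 CPM; floors cover counting error only.

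Columns were matched to samples by sex and replicate number. Rows with the same symbol were summed, which gave 48315 symbols, 110 of them from more than 1 row. Gene types and positions came from GENCODE M21 on GRCm38, in which 99.2% of the gene identifiers were found; positions of genes are given on that build, counted from 1. The main comparison was fitted with limma 3.58.1 in R 4.3.3, on log2(CPM + 1), over genes with a mean of at least 1 CPM in all 8 libraries, with an intensity trend, a two-sided moderated test and Benjamini-Hochberg adjustment at 0.05. A fold change is the difference of mean log2(CPM + 1), female minus male as labelled, and understates the change of low genes. Gene lists (45, fixed before the data were examined) were tested with limma's camera at a preset inter-gene correlation of 0.01 and with its variance trend, an option set after a first look at the results; 44 lists had at least 4 measured members. Camera with an estimated correlation and fry, which asks whether the genes of a list move one way on balance, were run beside it. Summed reads of lists and the sex-linked genes were compared by exact two-sided permutation tests of 4 against 4, whose 70 arrangements allow no p below 0.0286. On simulated data with the spread of these libraries, the limma comparison of 15564 genes recovered 97% of the genes changed 2-fold and 100% of those changed 4-fold, with 8 false calls. The simulation drew genes independently, without an effect of the replicate number or libraries against their label, and changed no gene of low level. It therefore does not show that a 2-fold change would have been found in the real libraries. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used for the rest.

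The deviations from the mean of the labelled sex correlated between libraries of the same number at 0.288, 0.492, 0.531 and 0.592 for numbers 1 to 4. All 4 lie above the required 0.1, so numbers were taken to pair the libraries; the pairing comes from the data, as the labels do not say what a number marks, and the library labelled female 1 correlated best with male 3. A fit with the number as a block is given beside a result where it changes the call. The libraries labelled female 1 and female 3 were compared by a chi-square test per gene on 12579 coding genes with at least 50 reads in the pair, with reads taken as the value divided by the step and rounded. Between them 1.04% of genes differed at p below 0.001, where sampling alone gave 0.0795%, so they differed by more than sampling noise and were kept as 2 libraries. The other 27 pairs of libraries differed in between 9.12% and 31.4% of genes. A difference beyond sampling does not show that female 1 and female 3 are independent. If both came from 1 tissue, n = 4 overstates the replication of the libraries labelled female.

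Genes named in the text followed a rule fixed before the data were examined: the Y-linked genes and Xist; up to 12 genes per direction that passed the threshold without overlap of the labelled sexes, or else the 5 with the smallest p, named as not passing; in each list described, up to 3 members that passed, or else the 2 with the highest mean; the 10 genes with the highest mean; and Prlr, Ptgds, Calca and Esr1. Alternatives fixed before the data were examined were pseudocounts of 0.1 and 5, no filter and a filter of 5 CPM, quantile normalization, median-ratio scaling, rescaling without mitochondrially encoded genes and the 20 most abundant genes, no trend, sample weights, the replicate block, and each library left out in turn. Alternatives added after the data were seen were a comparison without the 3 libraries whose sex-linked genes went against their label, the average of female 1 and female 3 as 1 library, protein-coding genes alone rescaled to the same total, the block with these genes, the block with numbers 2 and 4 alone or without each number, and reads per kilobase of coding length.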

Results

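The libraries were made to show which transcripts ribosomes occupied in mouse DRG labelled male and female, 4 libraries of each, under saline. Where reads lie in a gene was not tested, so reads on RNAs that are not protein-coding cannot be taken as footprints of translation. Protein-coding genes held between 78.3% and 93.8% of the assigned reads, and mitochondrial ribosomal RNA between 3.21% and 15.6%. Levels are in CPM (reads per 1000000 assigned reads), and a library is named by its labelled sex and number, because sex-linked genes went against the label in 3 of the 8 libraries. The libraries labelled female 1 to 4 held 5729311, 8535086, 11514364 and 7225966 assigned reads, and those labelled male 1 to 4 held 3697686, 7168173, 12714554 and 6781796.

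Transcripts of neurons, glia and connective tissue were among the most abundant coding transcripts, below Lars2, the highest coding gene. Among the 10 genes with the highest mean over all 8 libraries were mt-Rnr2 and mt-Rnr1, the mitochondrial ribosomal RNAs, at 60989 ± 32450 and 14728 ± 11473 CPM (SD, n = 8), Lars2, a mitochondrial leucyl-tRNA synthetase, at 28730 ± 26460 CPM, Map1b, a microtubule protein of neurons, at 10213 ± 1341 CPM, Gm43846 at 8763 ± 12246 CPM, Apoe, a lipid carrier made by glia, at 6249 ± 765 CPM, the collagen gene Col1a1 at 5177 ± 991 CPM, and Nefl, a neurofilament subunit, at 4829 ± 792 CPM. Lars2 differed 11.3-fold between its highest and lowest library and Gm43846 21.4-fold, whereas Apoe differed 1.48-fold. Lars2 lies on chromosome 9 from 123366927 to 123462666 and Gm43846, annotated as a sense intronic transcript, on chromosome 3 from 104957442 to 104958373. Per kilobase of coding length, Lars2 (10617 ± 9778 CPM) stayed at rank 1 among coding genes, while Map1b went from rank 2 to rank 39 at 1382 ± 181 CPM per kilobase. All reads of a gene were divided by its coding length, and where they lie in the gene was not tested. The rank of Lars2 therefore holds for reads and does not show coding footprints. The log2 level of Lars2 followed that of Gm15662, a gene outside the naming rule, across the 8 libraries (Pearson r = 0.973).

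Among cell type lists, pan-neuronal genes had the highest footprint level, a median over members of 662 CPM in libraries labelled female and 578 CPM in those labelled male. Fibroblast genes followed at 462 and 502 CPM. Satellite glia genes, led by Apoe and Sparc, had medians of 226 and 218 CPM, and myelinating Schwann cell genes, among them Pmp22, 165 and 170.1 CPM. Of the sensory neuron classes, non-peptidergic nociceptor genes such as Scn11a (1427 ± 105 CPM, n = 8) and Ret (729.5 ± 85.5 CPM) had medians of 223 and 232 CPM. Genes of myelinated mechanoreceptors and proprioceptors, led by Nefh at 2668 ± 214 CPM, had medians of 138 and 109.8 CPM. Those of peptidergic nociceptors, led by Calca, which encodes calcitonin gene-related peptide, had 102 and 83.4 CPM. Cold and C low-threshold neuron genes (Th, Trpm8) and itch neuron genes (Jak1, F2rl2) had medians between 15.6 and 19.3 CPM, and lymphocyte genes 0.808 and 0.917 CPM. Skeletal muscle genes, led by Ttn and Acta1, had medians of 426 and 310.2 CPM. No test was made of these levels. They are shares of reads with no correction for gene length, so the order of lists is not an order of ribosome density.

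**Figure D1:**
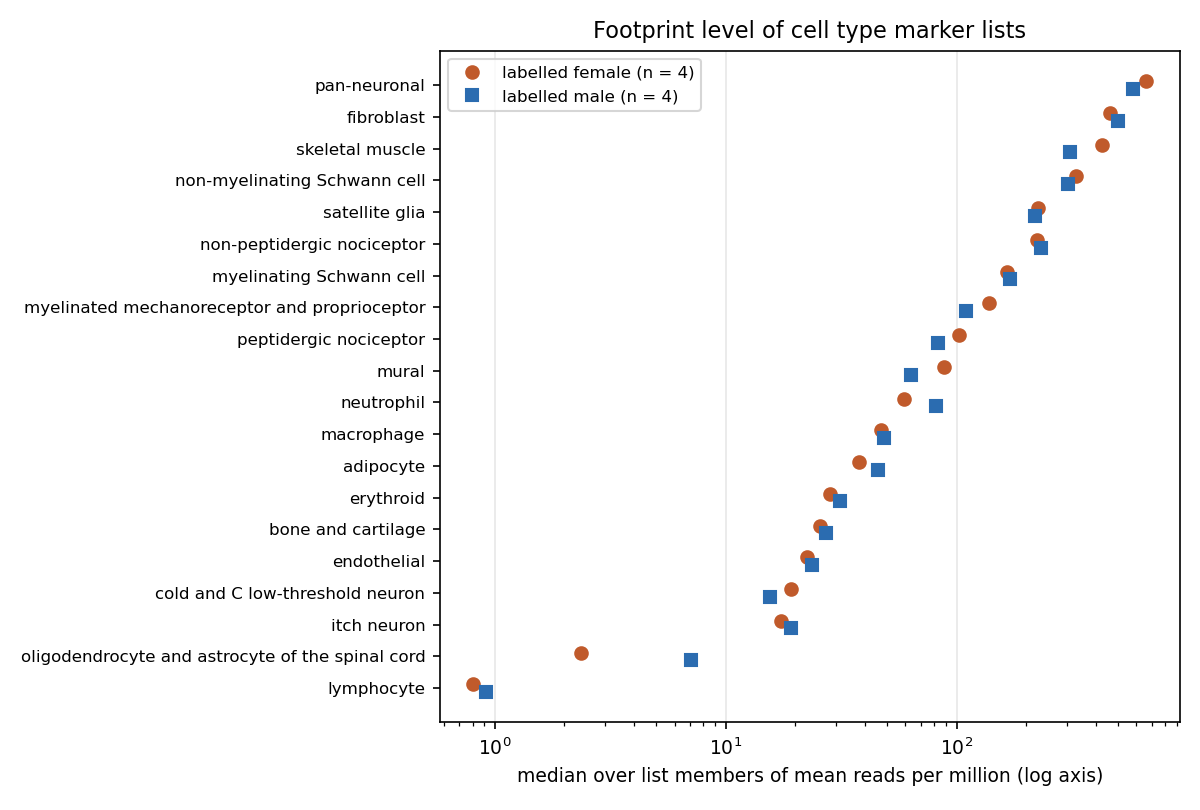
Footprint level of the cell type lists. Each point is the median over a list's genes of the mean CPM, on a log axis, for the 4 libraries labelled female (circles) and the 4 labelled male (squares). Pan-neuronal genes were highest at 662 and 578, and lymphocyte genes lowest at 0.808 and 0.917. Values are not corrected for gene length.

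Genes of the Y chromosome and Xist, the RNA that silences an X chromosome in female cells, were read first as a check of the labels. Ddx3y (chromosome Y, 1260771 to 1286629), an RNA helicase, was at 37.9, 54.1 and 39.96 CPM in male 2, male 3 and male 4 and at 0.117 and 0.138 CPM in female 2 and female 4, near the level of 1 read. In the library labelled male 1 it was at 1.62 CPM, and in the libraries labelled female 1 and female 3 at 55.2 and 61.9 CPM. Eif2s3y (chromosome Y, 1010543 to 1028847), Kdm5d (chromosome Y, 897788 to 956786) and Uty (chromosome Y, 1096861 to 1245759) split the libraries the same way, and the 4 genes summed to 2.70 CPM in male 1, 121 in female 1 and 138 in female 3. Xist (chromosome X, 103460366 to 103483254) was at 7.45 and 6.92 CPM in female 2 and female 4 and at 10.6 CPM in male 1. It was at 0.175 CPM in female 1 and listed at 0 in female 3, where 3 reads would be 0.261 CPM. Between labelled sexes the summed Y-linked level was 64.9 ± 74.8 CPM in female and 78.3 ± 52.7 CPM in male libraries (SD, n = 4; exact permutation p = 0.857). Xist was at 3.64 ± 4.10 and 2.90 ± 5.12 CPM (n = 4; exact permutation p = 0.971). Every direction below is thus between labels, and 3 libraries carry sex-linked genes of the other sex.

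**Figure D2:**
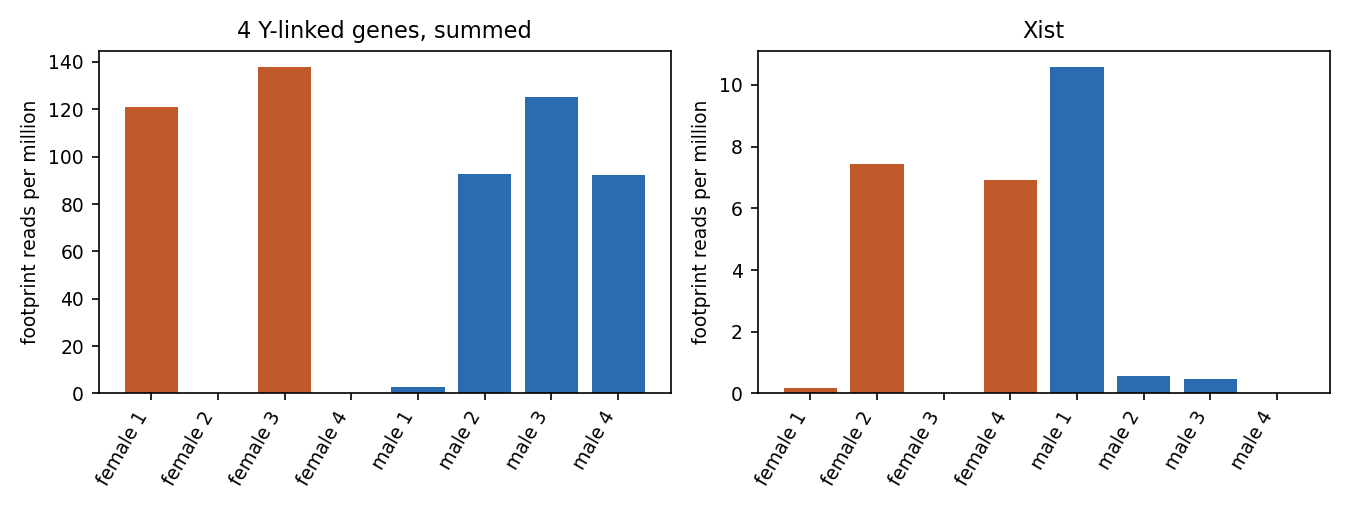
Sex-linked genes per library. Bars give CPM in each of the 8 libraries for the sum of 4 Y-linked genes (left) and for Xist (right), coloured by the labelled sex. Male 1 has 2.70 for the Y-linked genes and 10.6 for Xist, while female 1 and female 3 have 121 and 138 for the Y-linked genes.

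No gene passed between the labelled sexes without the replicate block, and with it 10 were higher in female and 17 in male. Without the block, of 15720 genes tested with limma, 0 were higher in libraries labelled female and 0 in those labelled male, with a smallest adjusted p of 0.372; at an unadjusted p under 0.05 there were 2099, of which 1877 were higher in female. That count was 807 without female 1, 795 without female 3, 966 without male 1, 1249 without male 4 and 3518 without male 3. It was 5157 with sample weights (smallest limma adjusted p = 0.0623), and 787 with female 1 and female 3 averaged as 1 library, an alternative chosen after seeing the data. Without the 3 libraries whose sex-linked genes went against the label it was 305, with 117 higher in female and 188 in male. By chance a share of about 0.05 of the genes tested would lie under this p. The counts without female 1, without female 3 and with both averaged lay near that share, and that of 305 below it. The excess thus depended on female 1 and female 3 both being in the fit, although fewer libraries also find fewer differences. The median log2 fold change of all genes was 0.15, and 0.017 after quantile normalization, with 1044 of 2015 genes at an unadjusted p under 0.05 higher in female. The groups did not overlap in 716 genes, 4.55% of those tested, where chance gives 2.86% if all 8 libraries are exchangeable, which the pairing by number and the closeness of female 1 and female 3 put in doubt. Without the 3 libraries whose sex-linked genes went against the label, an alternative chosen after seeing the data, 5 genes were higher in male: Ddx3y, Eif2s3y, Kdm5d, Uty and C7, a complement component (named after its values were seen; log2 fold change -2.46, limma adjusted p = 0.0135). The Y-linked genes among them follow from how the libraries were set aside.

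The genes with the smallest p did not pass without the block. On the female side these were Pmvk, an enzyme of the mevalonate pathway, at 46.5 ± 6.91 CPM in female against 28.5 ± 5.31 CPM in male libraries (SD, n = 4; log2 fold change 0.69, SE 0.16, limma adjusted p = 0.372), Synj2bp (log2 fold change 0.87), Rab27b, a GTPase of vesicle release (0.57), Zcchc17 (0.68) and Prps1, which makes phosphoribosyl pyrophosphate (0.58). On the male side they were mt-Nd4 and mt-Nd1, subunits of mitochondrial complex I, at log2 fold changes of -0.76 and -0.61, Rpph1, the RNA of ribonuclease P (-1.25), mt-Atp8, a subunit of ATP synthase (-0.76), and Ltb4r1, a leukotriene receptor (-0.69). mt-Nd4 was at 252 ± 21.03 CPM in female and 429 ± 56.2 CPM in male libraries. Rpph1 (chromosome 14, 50807449 to 50807767) was at 465 ± 48.6 and 1177 ± 546 CPM. Genes followed for a known interest in sex differences of pain did not pass: the prolactin receptor gene Prlr (log2 fold change -0.34, SE 0.24), Ptgds, a prostaglandin D synthase (0.074, SE 0.26), Calca (0.27, SE 0.14) and the oestrogen receptor gene Esr1 (0.077, SE 0.18). Ptgds and Esr1 had the other sign with median-ratio scaling, at -0.091 and -0.075.

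With the replicate number as a block, 10 genes were higher in female and 17 in male. The counts were 4 and 2 without number 1, 50 and 50 without number 2, 50 and 113 without number 3 and 44 and 82 without number 4, alternatives chosen after seeing the data. Fits with fewer numbers estimate the spread of a gene from very few libraries, so their higher counts are not taken as more differences. Of the 27 genes, 19 were not protein-coding, against 1641 of the 15720 tested (Fisher's exact test, two-sided, p = 2.0e-13); this was tested for the block with all 4 numbers alone. Rpph1 (limma adjusted p = 0.00382) and mt-Nd4 (adjusted p = 0.0312) were among those higher in male. Whether reads on the 19 RNAs that are not protein-coding came from ribosomes was not tested. Their calls are therefore of reads and not of translation. With protein-coding genes alone, rescaled, the block gave 0 genes in either direction, with 2763 at an unadjusted p under 0.05.

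Gene lists were compared to see which groups of genes moved against the rest. Camera with a preset correlation called 22 of 44 lists, 7 higher and 15 lower in female; with an estimated correlation and with fry 0 were called, so each call below rests on the preset correlation. Effects are given as the mean log2 fold change of a list minus that of the other genes. Mitochondrially encoded protein genes were lower in female libraries by this measure, at -0.53 (camera adjusted p = 5.2e-13; adjusted p = 0.536 with an estimated correlation). Of 12 measured members, 10 were lower in female, 0 passed over all genes without the block and 7 passed adjusted over the list alone, all lower in female; with the block mt-Nd4 passed over all genes (limma adjusted p = 0.0312). With the block and numbers 2 and 4 alone, mitochondrially encoded protein genes were at -0.16 (camera adjusted p = 0.00837, from a fit with very few libraries). Some of the 12 members had few reads: mt-Atp6, mt-Nd3, mt-Co3 and mt-Nd4l had means of 1.49, 4.98, 5.81 and 14.5 CPM over all libraries. In the effect of the list each of them weighs as much as a gene with many reads. mt-Cytb was at 1143 ± 105 CPM in female against 1783 ± 402 CPM in male libraries, and mt-Nd5 at 770.3 ± 21.8 against 1208 ± 277 CPM (SD, n = 4). Mitochondrial ribosomal RNA also lay higher in libraries labelled male, at 10.1% ± 4.51 of reads against 5.01% ± 1.98.

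Lists of the protein synthesis and energy machinery encoded in the nucleus were higher in female, relative to the other genes. Counts of members higher in female are not relative to the other genes, whose log2 fold changes also leaned to female (median of all genes 0.15). All 13 selenoprotein and all 15 skeletal muscle genes were higher in female too, without a call (camera adjusted p = 0.294 and 0.724). Cytosolic ribosomal protein genes were at 0.17 (camera adjusted p = 6.9e-06; adjusted p = 0.666 with an estimated correlation), with 75 of 80 members higher in female and none passing over all genes or adjusted over the list alone. Rpl4 was at 248 ± 29.3 and 207 ± 41.9 CPM and Rpl8 at 166 ± 7.20 and 132 ± 20.49 CPM. Translation initiation and elongation factors, led by Eef1a2 and Eef2, were at 0.18 with 37 of 37 members higher (camera adjusted p = 1.6e-05; adjusted p = 0.621 with an estimated correlation). Glycolysis genes, led by Aldoa and Pkm, were at 0.21 with 16 of 16 higher (camera adjusted p = 3.0e-04; adjusted p = 0.621 with an estimated correlation). Nuclear-encoded oxidative phosphorylation genes, among them Atp5b and Atp5a1, were at 0.12 with 72 of 75 higher (camera adjusted p = 2.3e-04; adjusted p = 0.777 with an estimated correlation), at 0.055 without male 4 and at 0.18 without the filter on low values; their call ended with the block without number 4, at 0.052 (adjusted p = 0.197). Heat shock and chaperone genes were at 0.30 with 15 of 16 higher, and 7 passed adjusted over the list alone (camera adjusted p = 2.3e-04; adjusted p = 0.621 with an estimated correlation). Hsp90ab1, its most abundant member, was at 4303 ± 781 and 3359 ± 499 CPM, and Hsp90b1 at 849.9 ± 128 and 876 ± 93.4 CPM. Without the 3 doubted libraries heat shock genes were at 0.13 (adjusted p = 0.0287) and glycolysis genes at 0.14 (adjusted p = 0.00715). Pan-neuronal genes, led by Nefl and Nefm, were at 0.22 with 16 of 16 higher (camera adjusted p = 0.00202; adjusted p = 0.666 with an estimated correlation); the call ended without the 3 doubted libraries (adjusted p = 0.247).

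Lists of connective tissue and of other cells were lower in female, relative to the other genes. Extracellular matrix genes were at -0.27 with 23 of 26 members lower (camera adjusted p = 2.3e-09; adjusted p = 0.536 with an estimated correlation), and at -0.13 without the 3 doubted libraries (adjusted p = 0.00504). Col1a1 was at 4505 ± 407 CPM in female and 5850 ± 960 CPM in male libraries, and Sparc at 3554 ± 279 and 4096 ± 722 CPM. Bone and cartilage genes, led by Comp and Col2a1, were at -0.39 (camera adjusted p = 3.1e-06; adjusted p = 0.321 with an estimated correlation). Fibroblast genes, led by Col1a1 and Col1a2, were at -0.26 (camera adjusted p = 2.5e-05; adjusted p = 0.536 with an estimated correlation). Neutrophil genes, led by S100a9 and S100a8, were at -0.34 (camera adjusted p = 3.1e-04; adjusted p = 0.628 with an estimated correlation), and at -0.14 without female 4, -0.18 without male 2, -0.60 without male 1 and -0.88 without the 3 doubted libraries (adjusted p = 2.6e-26); the call ended with the block without number 4, at -0.084 (adjusted p = 0.447). In these lists, 9 of 11 bone, 11 of 14 fibroblast and 11 of 12 neutrophil genes were lower in female. Macrophage genes (Cd74, Lyz2) were at -0.21, endothelial genes (Vwf, Cdh5) at -0.17 and non-myelinating Schwann cell genes (L1cam, Scn7a) at -0.21, with camera adjusted p of 5.7e-04, 0.00955 and 0.0122 and each with an adjusted p of 0.536 with an estimated correlation. Of their members, 11 of 16, 7 of 12 and 4 of 8 were lower in female. Without the 3 doubted libraries the calls of fibroblast (adjusted p = 0.109), macrophage (0.853) and endothelial genes (0.121) ended, and without the filter on low values those of endothelial (0.0831) and non-myelinating Schwann cell genes (0.152). With the block the call of endothelial genes ended without number 3 (0.0511) or 4 (0.111), that of non-myelinating Schwann cell genes without number 2 (0.181) or 4 (0.132), and those of macrophage (0.208) and endothelial genes (0.161) with numbers 2 and 4 alone. Oligodendrocyte and astrocyte genes of the spinal cord, led by Gja1 and Slc1a2, were at -0.64 with 10 of 10 lower (camera adjusted p = 2.7e-05; adjusted p = 0.536 with an estimated correlation), and at -0.20 without male 2, where Slc1a2 was at 139.9 CPM against at most 27.7 CPM in the other libraries. Their call ended with the block without number 2, at -0.11 (adjusted p = 0.340). Without the block none of the 44 lists had a member that passed over all genes.

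The remaining 7 calls lay closer to the threshold or changed with 1 library. Y-linked genes were at -1.24, and between -2.15 and -0.45 with 1 library left out (camera adjusted p = 0.0248; adjusted p = 0.621 with an estimated correlation), and the call ended without female 2, female 4, male 3 or male 4. X-linked genes known to escape inactivation, led by Usp9x and Ddx3x, were at 0.17 (camera adjusted p = 0.0433; adjusted p = 0.536 with an estimated correlation). Their call ended without female 2, female 4, male 2, male 3 or male 4, with effects between 0.10 and 0.24. Without the 3 doubted libraries, which were set aside for their sex-linked genes, Y-linked genes were at -4.47 (adjusted p = 3.8e-34) and X-escape genes at 0.35 (adjusted p = 1.5e-05). Adipocyte genes, led by Car3 and Cfd, were at -0.22 (camera adjusted p = 0.0256; adjusted p = 0.696 with an estimated correlation). Their call ended without female 1, female 3, male 1 (0.049) or male 3, and they were called higher in female, at 0.33, without the 3 doubted libraries. For these 3 lists the call ended in all 4 rescalings. Mural cell genes, led by Cspg4 and Acta2, were at -0.13 (camera adjusted p = 0.0326; adjusted p = 0.621 with an estimated correlation), and the call ended without female 2, female 4 or male 1 (-0.0058). Genes of prostaglandin synthesis and signalling, led by Ptgds and Ptges3, were at -0.15 (camera adjusted p = 0.0334; adjusted p = 0.536 with an estimated correlation) and between -0.19 and -0.12 with 1 library left out; the call ended without female 3, female 4, male 2 or male 3. Those of myelinated mechanoreceptors and proprioceptors were at -0.11 (camera adjusted p = 0.0343; adjusted p = 0.666 with an estimated correlation) and between -0.14 and -0.074; the call ended without female 4, male 2 or male 3. Satellite glia genes were at -0.12 (camera adjusted p = 0.0381; adjusted p = 0.621 with an estimated correlation) and between -0.15 and -0.093; the call ended without female 1, female 2, female 3, male 2 or male 3 and with quantile normalization. For mechanoreceptor and satellite glia genes the mean log2 fold change (0.016 and 0.0022) and the median (-0.055 and -0.050) differed in sign, as they did for prostaglandin genes (mean -0.024, median 0.0020). Mural, prostaglandin and satellite glia calls also ended without the 3 doubted libraries, with adjusted p of 0.169, 0.260 and 0.260. Without the filter on low values these calls ended, except that of X-escape genes, which ended with a filter of 5 CPM and without the trend. With sample weights the calls of Y-linked, X-escape, mechanoreceptor and mural genes ended, and with female 1 and female 3 averaged those of adipocyte, prostaglandin and satellite glia genes. With the replicate block 17 of the 22 lists kept their call; mural, prostaglandin, mechanoreceptor, satellite glia and X-escape lists did not, and skeletal muscle genes were called higher in female (camera adjusted p = 0.013; adjusted p = 0.859 with an estimated correlation; against 0.724 without the block).

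The other 22 lists did not pass. Itch neuron genes were at -0.13 (camera adjusted p = 0.0795) and myelinating Schwann cell genes at -0.13 (camera adjusted p = 0.102). Genes of sex hormone and prolactin receptors and their response were at 0.069 (camera adjusted p = 0.429). Peptidergic nociceptor genes were at 0.089 (camera adjusted p = 0.412), non-peptidergic nociceptor genes at 0.0096 (camera adjusted p = 0.892), and genes of the calcitonin gene-related peptide and neuropeptide system, with Tac1 at 115 ± 23.9 and 74.8 ± 23.5 CPM, at -0.013 (camera adjusted p = 0.805).

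Summed reads of 11 lists were compared to see how the libraries were composed, and none passed after adjustment over the 11. The mitochondrially encoded genes summed to 4143 ± 318 CPM in female and 6381 ± 1248 CPM in male libraries (SD, n = 4; exact permutation p = 0.0286, the smallest possible, adjusted p = 0.157). Every library labelled male was above every library labelled female. Non-myelinating Schwann cell genes summed to 3835 ± 187 and 4358 ± 180.3 CPM (n = 4; exact permutation p = 0.0286, adjusted p = 0.157). Peptidergic nociceptor genes summed to 1617 ± 117 and 1395 ± 148 CPM and cold and C low-threshold genes to 288 ± 20.8 and 240.5 ± 25.0 CPM (n = 4; exact permutation p = 0.0571 for both). Cytosolic ribosomal protein genes summed to 4153 ± 21.2 and 3441 ± 629 CPM and pan-neuronal genes to 20857 ± 2175 and 16783 ± 3464 CPM (n = 4; exact permutation p = 0.114 for both). Itch neuron, satellite glia, myelinated mechanoreceptor, myelinating Schwann cell and non-peptidergic nociceptor genes had exact permutation p between 0.114 and 0.886. With the sexes exchanged within replicate numbers no p can be below 0.125, which mitochondrially encoded, pan-neuronal, peptidergic, itch, cold and C low-threshold and non-myelinating Schwann cell genes reached, each with the same sign in all 4 pairs. The other lists were at 0.250 or above.

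**Figure D3:**
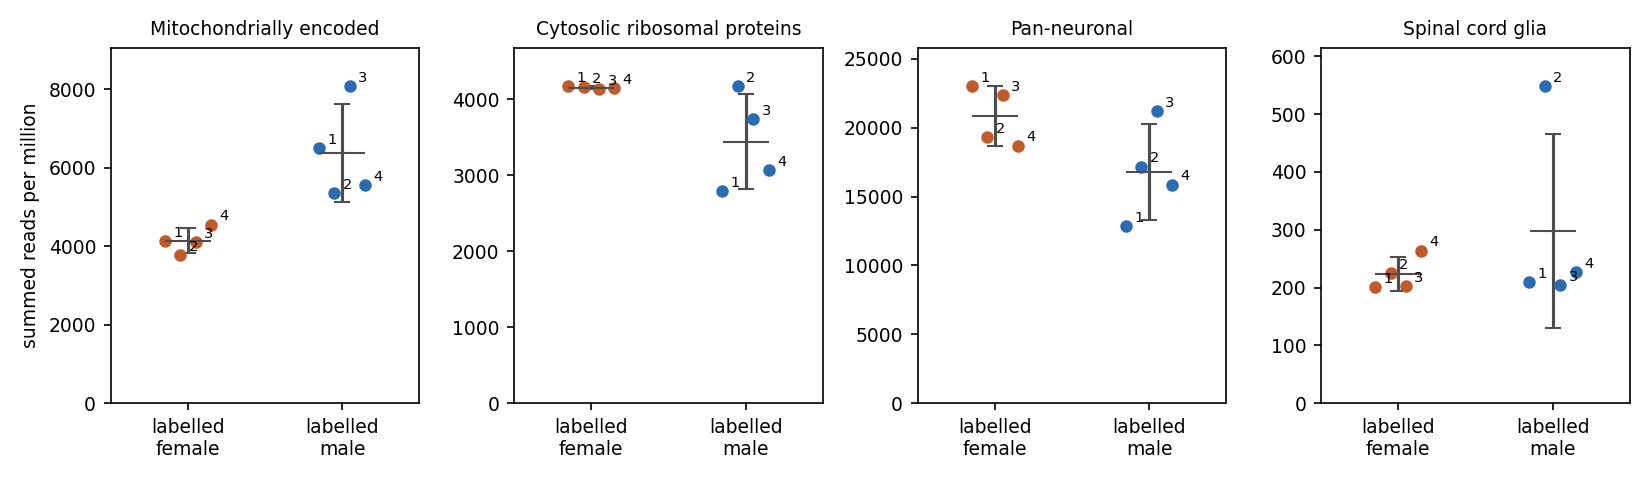
Summed CPM of 4 gene lists in each library, with the mean and SD of the 4 libraries of each label; digits are replicate numbers. For mitochondrially encoded genes the libraries labelled male lie above those labelled female (means 6381 and 4143), and for spinal cord glia male 2 stands apart at 549.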

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

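All tests of the explanations below were chosen after the results were seen. Of 266 groups of 4 libraries looked at, 24 had 1 library far from the other 3, where chance, at about 1 in 20 groups, gives about 13.3.

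In libraries labelled male, Xist was at 10.6 CPM in male 1 and at most 0.558 in the others. Tsix was at 0.140 CPM in male 2, which is 1 read, and listed at 0 in the others. Gm43846 stood apart in both libraries of number 2, at 26716 CPM in female 2 and 30297 CPM in male 2. Also in female 2, mt-Nd4 (283.8 CPM), Pmp22 (5315 CPM), Hba-a1 (548 CPM), Igf2 (245 CPM), Cntf (189.5 CPM) and Hist1h1e (138 CPM) were high, and Ddx3x (230.5 CPM), Hsp90b1 (659.6 CPM) and the summed cold and C low-threshold neuron genes (257 CPM) low. In male 2, Ptgds (3875 CPM), Gja1 (256 CPM), Slc1a2 (139.9 CPM) and the summed oligodendrocyte and astrocyte genes of the spinal cord (549 CPM) were high. Cspg4 was low in male 3 (168 CPM), Nr4a1 high in female 1 (63.7 CPM) and H2-D1 high in male 4 (307 CPM). By class of RNA, mitochondrial transfer RNA was high in male 2 (0.168% of reads), reads on rows outside the annotation in female 2 (0.8291%), and other RNA in female 2 (4.46%) and male 2 (4.42%).

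Sex-linked genes went against the label in male 1, female 1 and female 3. Male tissue mixed into female 1 and female 3 would have left Xist in place, but the higher of their levels was 2.52% of that in female 4. Reads of X-linked homologs are also argued against, since the Y-linked genes summed to at most 0.351 CPM in female 2 and female 4. An exchange of male 1 with female 1 or female 3 may account for 2 of the libraries: both hold Y-linked genes, the lower at 121 CPM, and male 1 has them at 2.70 CPM. They are thus low in male 1 but not absent, as that sum lies above the 0.351 CPM of female 2. The remaining library would need a wrong label of its own, which was not tested; Mbtd1 and Prim1, picked after their values were seen, were at 11.1 and 13.3 CPM in male 1, 14.7 and 19.5 in female 1 and 906 and 770.4 in female 3 (746 and 687.6 in male 3), a tie to the number that speaks against an exchange of male 1 with female 3 as finished libraries and leaves an exchange of tissue before library preparation open.

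By the share of coding genes that differed, female 1 and female 3 were closer to each other than any other pair of libraries. By correlation of log2 levels across genes they were not, at 0.98868 against a highest value of 0.98907. A single library deposited under both names is argued against by the 1.04% of coding genes that differed at p below 0.001, where sampling alone gave 0.0795%. A likeness of numbers 1 and 3 as batches is argued against by the 16.1% of coding genes that differed between male 1 and male 3. A candidate explanation is 1 tissue made into 2 libraries in different batches: 49 genes were over 2-fold apart between female 1 and female 3 at p below 0.001, and of the 43 with at least 50 reads in male 1 and male 3, 88.4% (95% exact interval 74.9% to 96.1%) differed the same way between male 1 and male 3, against 54.2% of the other genes. The lower end of the interval lies under the share asked of that explanation. The interval also takes the 43 genes as independent, although all come from the same libraries, and may be too narrow. The explanation therefore stays open: the value ties the difference to the number and does not show that the tissue was the same.

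Mitochondrially encoded genes followed the label and not the sex-linked genes. The sex of the animal, as sex-linked genes show it, is argued against by the 3 libraries whose sex-linked genes go against the label, since all 3 lay on the side of their label: male 1 at 6510 CPM, female 1 at 4123 and female 3 at 4112. Non-coding RNA in the denominator is argued against, as the lowest library labelled male stayed 1.17 times the highest labelled female after rescaling to protein-coding genes. More mitochondrial RNA of any kind stays open: mitochondrial ribosomal RNA was 2.02 times as high in the mean of libraries labelled male, but the labels overlapped. Mitochondrial transfer RNA went the other way in the mean, at 0.114% ± 0.130 of reads in libraries labelled female and 0.0834% ± 0.0572 in those labelled male. That direction rested on female 2, at 0.303%, as the other libraries labelled female held between 0.0273% and 0.0954%. A difference in handling between the 2 deposited tables cannot be told apart from the label, because 0 tables hold libraries of both.

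Other splits of the 8 libraries were compared with the labelled one. For genes higher in female and for genes higher in male the labelled split gave 0, so all 35 splits gave as many whatever they held, and the count says nothing about chance. The highest other split, female 1, female 3, female 4 and male 3 against the rest, gave 1107 genes in 1 direction, which points to a structure of the libraries other than the labels. For gene lists the labelled split gave 22 calls and the other splits between 3 and 18, so 1 of 35 splits gave as many at the preset correlation without the block. Every split thus called some lists, so a call by itself does not tie a list to the label. The comparison also takes the libraries as exchangeable, which the pairing by number and the closeness of female 1 and female 3 put in doubt. With the replicate block the labelled split gave 27 genes and 18 lists, and the highest of the other exchanges within numbers 0 genes and 17 lists; with 8 exchanges, 1 of them the real one, the share cannot be under 0.05.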

How the results depend on the processing

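Settings with protein-coding genes alone, without the 3 doubted libraries, with female 1 and female 3 averaged, and the block with fewer numbers or with coding genes were chosen after seeing the data. The replicate block moved genes higher in female from 0 to 10 and genes higher in male from 0 to 17. With numbers 2 and 4 alone the block gave 60 and 157. Without numbers 1, 2, 3 and 4 in turn, 4, 50, 50 and 44 were higher in female and 2, 50, 113 and 82 in male. These fits estimate the spread of a gene from very few libraries. Their smallest limma adjusted p was 9.9e-103 with numbers 2 and 4 alone, and 5.5e-36 and 1.3e-34 without numbers 3 and 4. So few libraries cannot carry such values, and higher counts are not taken as more differences. The cause of the higher counts was not tested. Without the 3 doubted libraries 5 genes were higher in male; 4 of them are Y-linked and follow from how the libraries were set aside, which leaves C7. In all other settings both counts stayed at 0, also with each library left out. Called lists numbered between 16 and 23 with each library left out, against 22. They numbered 15 without the filter on low values (8 higher and 7 lower in female; 14 of the 22 kept), 20 with sample weights (18 kept), 19 with female 1 and female 3 averaged (19 kept) and 13 under the block without number 4. Of the 22 lists, 7 kept their call at the preset correlation in every setting that measured them: mitochondrially encoded, cytosolic ribosomal protein, translation factor, glycolysis, heat shock, extracellular matrix, and bone and cartilage genes. In the main fit none of these 7 was called with an estimated correlation or with fry. Over 19 named genes, 474 of 502 settings kept the direction of the log2 fold change. Besides the counts of genes and the lists named with it, the block changed no call of a list; for sums no exact p can be below 0.125 with the block.

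Sample weights reversed the log2 fold change of Ddx3y (0.094), Eif2s3y (0.057), Kdm5d (0.21), Uty (0.10) and Xist (-0.19). Under the block, Kdm5d was at 0.19 without number 2 and 0.019 without number 4, Uty at 0.063 without number 4, and Xist at -0.29 and -0.47 without numbers 2 and 4. With each library left out Xist ranged from -0.11 to 1.17, Kdm5d from -1.78 to -0.15, Uty from -1.77 to -0.18, Ptgds from -0.057 to 0.36 and Esr1 from -0.099 to 0.16. Ptgds was at -0.091 with median-ratio scaling, -0.040 rescaled without abundant genes, -0.025 with coding genes with or without the block, and -0.087 under the block without number 4. Esr1 was at -0.073, -0.075 and -0.029 with quantile, median-ratio and rescaled values, -0.015 with coding genes with or without the block, and -0.13 under the block without number 4. The adipocyte list ranged from -0.45 to 0.049 with each library left out, and was at 0.33 without the 3 doubted libraries, 0.54 under the block with numbers 2 and 4 and 0.11 under the block without number 1.

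With each library left out, the difference in summed reads, female minus male, ranged from -68.9 to 115 CPM for non-peptidergic nociceptor genes, from -300.1 to 37.3 for myelinated mechanoreceptor and proprioceptor genes, from -1539 to 1052 for myelinating Schwann cell genes, from -38.6 to 8.11 for Y-linked genes and from -0.537 to 3.29 for Xist. Rescaled without abundant genes, non-peptidergic nociceptor genes were at -360.3 CPM. Of 90 levels of lists, those that moved by more than the spread with 1 library left out ranged from 222 to 227 CPM for satellite glia, 14.95 to 16.8 for prostaglandin genes in female and 15.8 to 18.8 in male, 16.9 to 19.3 for integrated stress response targets, 111 to 118 for nuclear-encoded oxidative phosphorylation, 13.7 to 14.8 for cytokines, and 62.0 to 75.7 in female and 60.8 to 69.99 in male for selenoproteins. With the median per library, cytokines were at 13.9 CPM. Male 1, at 3697686 reads, has the highest floor, 0.811 CPM, and limits what can be said of low genes.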

Other observations

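The test in the last paragraph was written before its result was seen; the remaining values were picked after they were seen. Skeletal muscle genes varied between libraries, summing to 12453 CPM in female 1, 12355 in female 3 and 10328 in male 1, the 3 libraries whose sex-linked genes go against the label, and to between 4090 and 7785 CPM in the others. Central glia genes in male 2 included Mobp at 25.1 CPM, Mog at 19.4 CPM and Aqp4 at 37.5 CPM, where the other libraries had at most 3.87, 4.28 and 15.04 CPM. Aldh1l1, a gene of the same list, was at 23.7 CPM in male 2 and at up to 26.5 CPM in other libraries.

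Mbtd1 and Prim1 followed the replicate number in both labelled sexes. Mbtd1 was at 14.7 and 11.1 CPM in female 1 and male 1, at 906 and 746 CPM in female 3 and male 3, and at 1044 and 1223 CPM in female 4 and male 4. Prim1 was at 19.5 and 13.3 CPM, 770.4 and 687.6 CPM, and 922 and 992.5 CPM in the same libraries.

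Some mitochondrially encoded genes were near 0 in every library. mt-Co2 was at 0.224 CPM, mt-Atp6 at 1.49 CPM and mt-Co3 at 5.81 CPM in the mean of 8 libraries, while mt-Cytb was at 1463 CPM. A candidate explanation is that reads shared with nuclear copies of mitochondrial DNA were not counted. Of the 30-base words of mt-Co2, 100% also occur in annotated nuclear transcripts, and of mt-Cytb 7.35%. Across the 13 genes, which are not independent replicates, the level per kilobase was lower where the share of such words was higher (Spearman rho = -0.786, permutation p = 0.00217). mt-Co1, at 64.8% shared words and 870.5 CPM, shows that a large shared part does not by itself bring a gene to 0.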
